A study of Mus musculus with 4 samples.

How the data were processed

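TT-seq libraries of mouse ES cells, 2 labelled Supt3 WT and 2 labelled Supt3 KO, were analysed from gene tables. Per the labels' protocols, labelled RNA was purified and fragmented, S. pombe labelled RNA served as spike-in, and stranded libraries were made without ribosomal depletion; the labels also name polyA RNA as the molecule. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 1.10, STAR 2.5.3, HTSeq 0.6.1p1, DESeq2 1.16.1 and the mm10 build. The strand setting, the counted feature and the annotation release are not given in the sources used here, so values of overlapping and antisense genes are uncertain.

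The deposited values are raw counts per gene for 54146 mouse and 7259 S. pombe genes. The authors' deposited comparison table repeats the raw counts (100% of values equal), and adds normalized signal values (raw counts divided by a size factor per library), a log2 fold change of KO over WT that is shrunken by a beta prior per the name the authors gave the table, and p-values. Its size factors equalled the DESeq2 median-of-ratios factors of the S. pombe counts to within 2.22e-16. No row named no gene, and all columns were used. Coordinates are those of the deposited table; of its gene IDs, 54079 are in GENCODE M21 and 52824 have the same coordinates there.

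Library totals were 17.7 M, 22.9 M, 17.9 M and 22.2 M counts (M, 1e6), mouse and S. pombe together, for WT replicates 1 and 2 and KO replicates 1 and 2. Replicates were numbered in accession order, and the labels give no pairing. The numbers fall together with the pairs of fewer and more counted reads. Counts of the WT pair differed by a chi-square of 6.05 per degree of freedom and those of the KO pair by 10.6, so no library was a duplicate. Whether PCR copies were removed is not given in the sources used here, and counting error alone is smaller than the spread between libraries.

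Genes were kept by edgeR's filterByExpr (minimum count 10, genotype groups), which left 16789. Both fits used edgeR 4.0.16 quasi-likelihood tests (R 4.3.3) with Benjamini-Hochberg adjusted p under 0.05. The spike-in fit took the S. pombe total times its TMM factor as library size, and the TMM fit used TMM factors of mouse genes. The standard error is the log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.363 in the spike-in fit and 0.0952 in the TMM fit. Gene lists (38, of which 37 had a tested member) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. With an estimated correlation 0 lists were called (1 at an unadjusted p under 0.05), and fry called 0 for a common direction (8 unadjusted) and 13 for change in either direction. The test of total output was an exact permutation test. Counts per chromosome were tested with Fisher's exact test over chromosomes and directions.

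The groups, tests, gene lists, most alternatives and the naming rule were set before the data were examined. Named were Supt3; in each fit the 10 largest changes per direction among called genes with both KO libraries on one side of both WT libraries, a mean of at least 2 CPM, a protein-coding or lincRNA biotype and a symbol that is not a predicted model; up to 4 called members of each list, or up to 2 of the most abundant where none was called; SAGA subunits as a count; and the 5 most abundant genes. One gene that the rule gives is not reported here. Alternatives were DESeq2 1.42.0, limma voom, other filters, other scalings and each library left out. Fits with a single library in one genotype assume that it varies like the other genotype's pair.

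The scan of each chromosome (genes of at least 2 CPM, intervals of at least 20 genes, 1000 permutations of gene order, shifts over 0.3 kept) was added after the data were seen and written in Python 3.11.15 with numpy 2.4.6. It was tested on simulated data, where it found 5 of 5 blocks of 60 genes shifted by 0.585 and called 0 of 5 unshifted runs. The simulated runs were gene values in shuffled order, as in the permutation test itself. They do not show how the scan treats neighbouring genes that vary together. In the scans between libraries of the same genotype, which keep gene order, the permutation test passed on several chromosomes, mostly with shifts under 0.3. Scans between libraries of the same genotype were the control; on chromosome 7 both placed an interval of 20 genes, Zim1 to Zfp551, with a shift of -0.49 in WT and -0.47 in KO (permutation, adjusted p = 0.00499 and 0.0150), and between the KO libraries the scan also placed Traip to Qars on chromosome 9 (-0.31, permutation, adjusted p = 0.0257). The edgeR fits were tested on simulated counts of 16789 genes with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. The TMM fit called 0.0785% of unchanged genes. In the same simulated counts camera called the 1 changed list and 0 of 38 others. Genes were simulated independently of each other and the lists were random, so this does not test lists whose genes vary together. The estimated correlation was 0.35 in the naive pluripotency list and 0.44 in the primitive endoderm list.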

Results

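Nascent RNA was profiled by TT-seq in mouse embryonic stem (ES) cells grown in LIF and serum. Cells are given 4-thiouridine (4sU) in this assay, so that the purified labelled RNA reports ongoing transcription rather than the accumulated RNA pool. The design compared wild-type (WT) cells with cells mutant for Supt3, here KO as labelled, with 2 libraries of each genotype. Supt3 encodes a core subunit of SAGA, a transcriptional coactivator complex. 4sU-labelled RNA of the fission yeast S. pombe had been added as a spike-in. Counts assigned to mouse genes were 13.5 M and 19.4 M in WT replicates 1 and 2, and 13.1 M and 18.4 M in KO replicates 1 and 2. The corresponding S. pombe counts were 4.16 M, 3.46 M, 4.84 M and 3.79 M. The most abundant mouse genes were Gm26917, which took 0.687% of all mouse counts, Jarid2 (0.416%), mt-Nd5 (0.349%), mt-Cytb (0.316%) and mt-Nd1 (0.308%). Nothing in the labels says whether the libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

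Supt3 was still transcribed in the libraries labelled KO. Its level was 153 ± 7.74 CPM in WT and 132 ± 11.6 CPM in KO (SD, n = 2 each), where CPM are counts per 1e6 mouse counts scaled by the trimmed mean of M-values (TMM). The single libraries stood at 148 and 159 CPM in WT and at 123 and 140 CPM in KO. The log2 fold change of KO over WT was -0.22 ± 0.10 (SE), and it did not pass the edgeR test (adjusted p = 0.232). Leaving out KO replicate 1 gave a log2 fold change of -0.13. Supt3 (ENSMUSG00000038954) spans chromosome 17 from 44777152 to 45119290 on the plus strand of mm10. The mutant allele is not described in the labels, and a count over the whole gene does not show whether a functional transcript is made, so this level does not check the genotype. Without KO replicate 2 the value was -0.31. Supt3 passed the edgeR test (adjusted p = 0.0111) with a batch term for library depth that was added after the data were seen. That term was defined from the same data and leaves 1 residual degree of freedom. Its p-values and numbers of calls, here and below, are therefore weak evidence.

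The spike-in asks whether total nascent RNA output differed between the genotypes. The libraries held 3.25 and 5.60 mouse counts per S. pombe count in WT, and 2.71 and 4.86 in KO. On the log2 scale the mean was 2.09 ± 0.56 in WT and 1.86 ± 0.60 in KO (SD, n = 2 each). The difference of -0.24, a ratio of 0.849, was smaller than the gap between libraries of the same genotype, which was 0.79 in WT and 0.84 in KO (exact two-sided permutation test, p = 0.667, where the smallest p this design allows is 0.333). Between the pair of libraries with fewer counted reads the difference was -0.26, and between the pair with more it was -0.21. These pairs were defined from the data. Without WT replicate 2 the sign turned (0.16), as it did without KO replicate 1 (0.19). Transcripts of the mitochondrial genome took 2.11% and 1.53% of mouse counts in WT and 1.47% and 1.67% in KO.

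**Figure D1:**
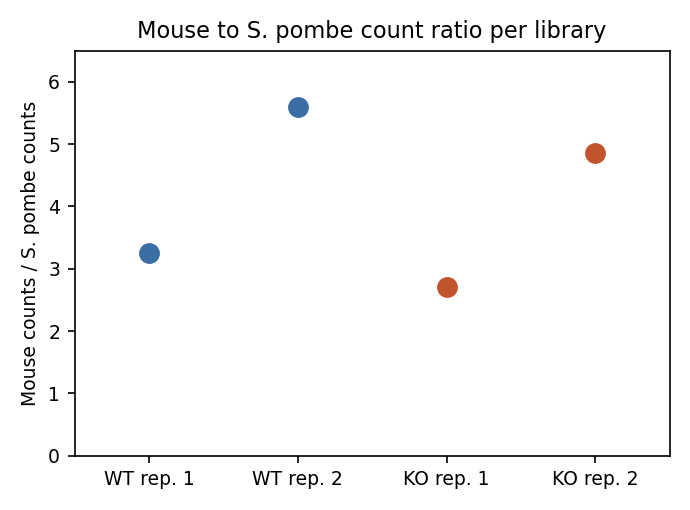
Mouse counts per S. pombe count (vertical axis, a ratio without unit) in each of the 4 libraries (horizontal axis), with WT in blue and KO in orange. The libraries of each genotype lie further apart (3.25 and 5.60 in WT, 2.71 and 4.86 in KO) than the genotypes do on average.

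Relative to the bulk of nascent transcripts, Meg3, Rian, Mirg and 8 of 20 naive pluripotency genes fell in KO, and 13 of 20 primitive endoderm genes and the keratin genes Krt8 and Krt18 rose. With TMM scaling, 1355 of 16789 tested genes differed in edgeR's quasi-likelihood test at an adjusted p under 0.05, of which 680 were higher and 675 lower in KO. A change of at least 2-fold was seen for 208 of the higher and 310 of the lower genes. The largest increases under the naming rule were those of Plagl1, an imprinted zinc finger gene, which rose by 2.45 ± 0.20 on the log2 scale from 4.71 ± 1.11 to 25.4 ± 4.17 CPM (SD, n = 2 each, adjusted p = 0.000959), and of Ankrd1, a target of SRF and YAP (2.18 ± 0.41). Stmn4 (2.14), Cpb2 (2.08), Xist (2.02), Cryab (1.87), Rassf9 (1.77) and Spesp1 (1.76) followed, together with Krt8 and Krt18. Stmn4 and Cpb2 lie in a stretch of chromosome 14 in which most genes were higher, as given further on. Xist, the long RNA of X inactivation, was low in both genotypes, at 1.91 ± 0.41 CPM in WT and 7.78 ± 5.05 CPM in KO, and its log2 fold change was 1.161 without KO replicate 1. That of Ankrd1 ranged from 1.57 without WT replicate 2 to 2.94 without WT replicate 1. The largest decreases under the naming rule were those of the Y-linked Zfy1 (-2.98 ± 0.20, from 26.7 ± 0.89 to 3.31 ± 1.11 CPM, adjusted p = 0.000665) and of Catsperg1 (-2.57). Under the same rule Meg3 (-2.57) and Mirg (-2.54) came next, then the antiviral Oas1g (-2.35), Pla2g4e (-2.15), Pramel7 (-2.11), Olfr836 (-2.05), the X-linked Usp26 (-2.01) and Slc3a1 (-1.98). Slc3a1 lies in a stretch of chromosome 17 in which most genes were lower. Without WT replicate 2 the test called 379 higher and 439 lower genes, and without KO replicate 2 it called 1481 and 1342. A batch term for the pairs of fewer and more counted reads, added after the data were seen, gave 2214 and 2093, which included all 1355.

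**Figure D2:**
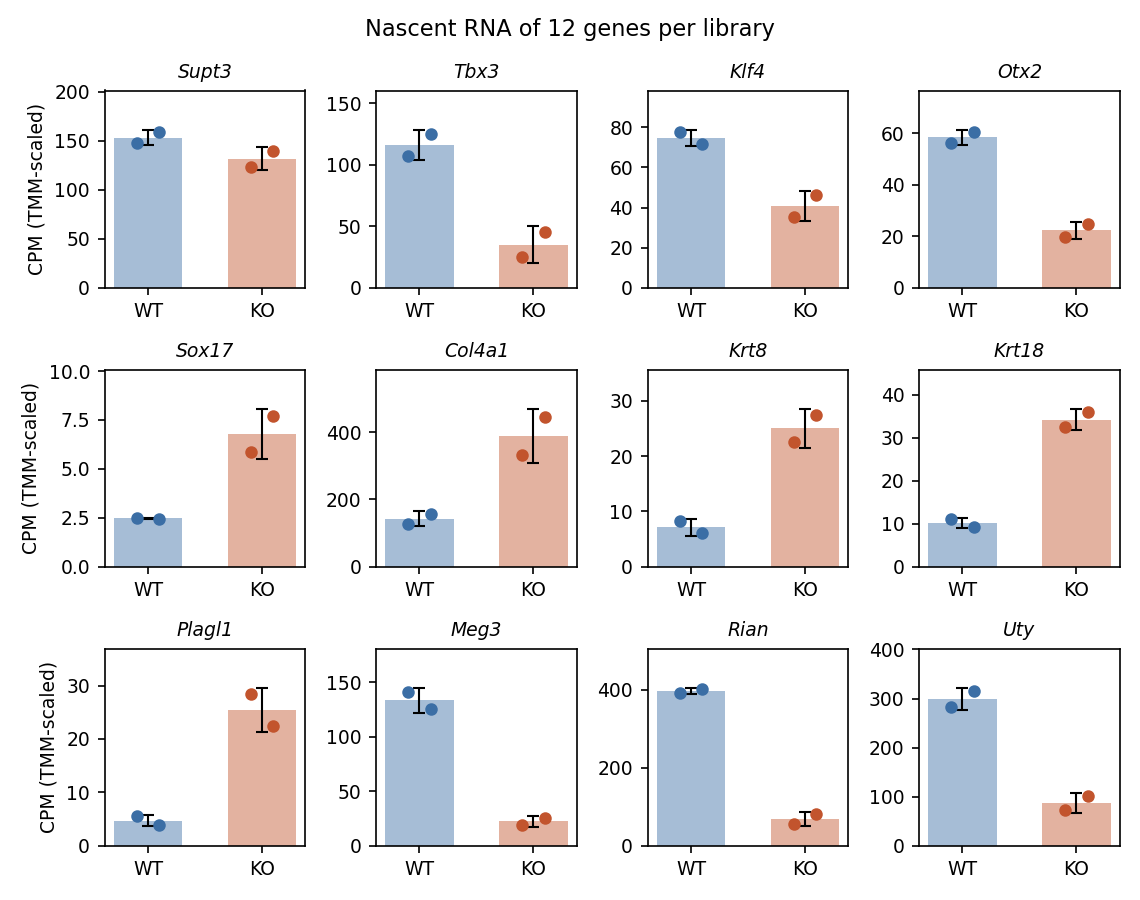
TMM-scaled CPM (vertical axes, each from 0) of 12 genes in WT (blue) and KO (orange), where bars are means, error bars the SD of 2 libraries and points the single libraries. Supt3 was not called, Tbx3, Klf4, Otx2, Meg3, Rian and Uty were lower in KO, and Sox17, Col4a1, Krt8, Krt18 and Plagl1 were higher.

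Several naive pluripotency genes fell while no core pluripotency gene was called. Of 20 naive genes tested, 8 were lower, none was higher and 12 did not pass; adjusted over the list alone, 13 were lower and 1 was higher. Among the called genes the largest decreases were in Tbx3 (from 116 ± 12.2 to 35.1 ± 14.9 CPM, log2 fold change -1.71 ± 0.23, adjusted p = 0.00401), Tcl1 (-0.97), Klf4 (-0.87 ± 0.13) and Tfcp2l1 (-0.73), which are transcriptional regulators of the naive state except Tcl1, a cofactor of Akt. The list's median was -0.62 (camera with a preset correlation, adjusted p = 2.95e-08), and the adjusted p was 0.630 with an estimated correlation. Without KO replicate 1 the median was -0.38 and Tfcp2l1 stood at -0.46. Tcl1 missed the threshold without WT replicate 2 (adjusted p = 0.0511). None of the 14 core pluripotency genes was called by edgeR, DESeq2 or limma voom, with 0 at an unadjusted p under 0.05 in edgeR, while the batch term gave 3 calls, Sall4 among them (adjusted p = 0.00913); the list's median was 0.01, and its most abundant members were Trim71 (969 ± 37.0 CPM in WT, 982 ± 93.3 in KO) and Sall4 (417 ± 40.9 and 356 ± 1.75). Of 18 targets of LIF and STAT3 signalling, 5 were lower and 1 higher (7 and 2 adjusted over the list alone), with a list median of -0.32 (camera adjusted p = 0.00720, and adjusted p = 0.757 with an estimated correlation). Klf4 and Tfcp2l1 are shared with the naive list, and Spry2, on the stretch of chromosome 14, rose by 0.62 ± 0.10. Spry2 was not called without WT replicate 2 (adjusted p = 0.105). Formative and primed genes went both ways, with 6 of 20 lower and 2 higher (7 and 5 adjusted over the list alone). Otx2, a regulator of the exit from the naive state, fell from 58.4 ± 2.94 to 22.2 ± 3.41 CPM (-1.39 ± 0.13, adjusted p = 0.00109), Zic5 fell by 1.04 and Zic2 by 0.97, and Wnt8a rose by 1.40. Zic2 and Zic5 lie beside each other near the end of chromosome 14. The formative list's camera call (adjusted p = 0.0479, and 0.802 as adjusted p with an estimated correlation) was lost without WT replicate 1 (adjusted p = 0.713), without KO replicate 2 (0.216) and without the genes of distal 14, distal 17 and Y (0.366). Its median of -0.11 ranged from -0.24 without WT replicate 2 and -0.20 without KO replicate 1 to 0.0367 without WT replicate 1 and 0.0714 without KO replicate 2. Wnt8a was not called without WT replicate 2 (adjusted p = 0.118).

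The called markers of extraembryonic lineages were all higher in the edgeR fit of all libraries. Of 20 primitive endoderm genes, 13 were higher and none lower (16 and 0 adjusted over the list alone), with a list median of 1.03 (camera adjusted p = 1.83e-20, and adjusted p = 0.630 with an estimated correlation). The basement membrane collagen genes Col4a1 and Col4a2 rose from 143 ± 21.1 to 388 ± 81.1 CPM and from 66.1 ± 5.08 to 175 ± 29.7 CPM, with log2 fold changes of 1.44 ± 0.16 and 1.40 ± 0.13. Sox17, an endoderm transcription factor, rose by 1.46 ± 0.24, and the receptor gene Pdgfra by 1.30 ± 0.22. Of 15 trophoblast genes tested, 6 were higher and none lower (6 and 1 adjusted over the list alone), with a median of 0.88, or 0.58 without WT replicate 2 (camera adjusted p = 2.69e-06, and adjusted p = 0.630 with an estimated correlation). The epithelial keratin genes Krt8 (7.11 ± 1.55 CPM in WT) and Krt18 (10.1 ± 1.19 CPM in WT) rose by 1.83 ± 0.19 and 1.76 ± 0.14, Krt7 by 1.30 ± 0.29 and Cdx2, a trophoblast regulator, by 2.21 ± 0.52 from 0.25 ± 0.06 CPM. Cdx2 was not called without WT replicate 2 or without KO replicate 1 (highest adjusted p = 0.225), nor was Krt7 without either WT library (highest adjusted p = 0.131) or in DESeq2, where the trophoblast list had 3 calls. Of 14 genes of the 2-cell-like state, 3 were higher and none lower (8 and 0 adjusted over the list alone), with a median of 0.99, or 0.60 without WT replicate 2 (camera adjusted p = 8.05e-05, and adjusted p = 0.757 with an estimated correlation). These were Zscan4e (1.62 ± 0.36), Zscan4b (1.58 ± 0.38) and Zscan4d (1.11 ± 0.28), near-identical copies between which reads cannot be assigned with certainty. Zscan4b was not called without WT replicate 2 (adjusted p = 0.157), and Zscan4d stood at 0.61 without KO replicate 1. The mesoderm list held 0 calls among 13 tested genes in edgeR, with 4 at an unadjusted p under 0.05, 1 call in DESeq2, 0 in limma voom and 4 with the batch term (camera adjusted p = 0.607). Among 10 neural ectoderm genes, Nes rose by 1.00 ± 0.22 and Olig3, below 1 CPM in both genotypes, fell by 2.47 ± 0.58 (camera adjusted p = 0.947; 2 and 1 adjusted over the list alone). Olig3 was called in just 1 of the 4 fits that leave out a library (highest adjusted p = 0.164). Of 15 fibroblast genes that feeder cells would carry, Thbs1 alone was called (1.27 ± 0.20, camera adjusted p = 0.245). The median of these 15 genes was 0.24 (quartiles 0.14 and 0.60), and 12 were positive. In edgeR 6 had an unadjusted p under 0.05, and the batch term gave 4 calls.

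**Figure D3:**
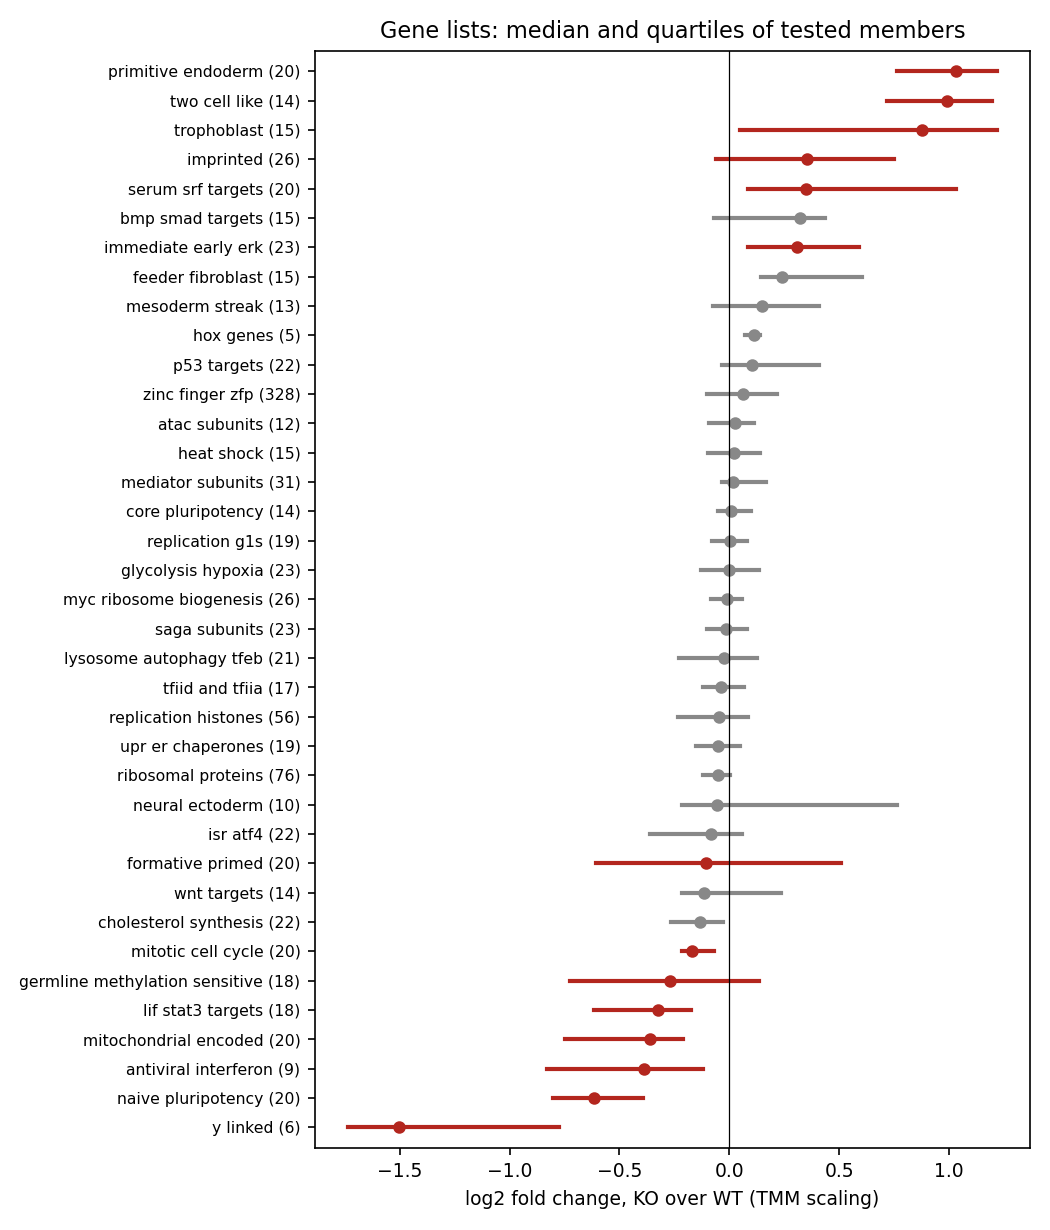
Median (point) and quartiles (line) of the log2 fold change of KO over WT with TMM scaling (horizontal axis) for the tested members of each gene list (vertical axis, number of members in brackets). The 14 lists called by camera with the preset correlation are red and the other lists grey, and none was called with an estimated correlation; primitive endoderm lies highest at 1.03 and the Y-linked genes lowest at -1.50.

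The called genes among cytoskeletal targets and immediate-early genes were all higher in the edgeR fit of all libraries. Of 20 targets of serum response factor (SRF), 8 were higher and none lower (8 and 0 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 6.72e-07, and adjusted p = 0.630 with an estimated correlation). Fhl2 rose by 1.30 ± 0.16, Tagln by 1.27 ± 0.20 and the matricellular gene Ctgf from 60.5 ± 8.58 to 126 ± 12.8 CPM (1.06 ± 0.12), next to Ankrd1. Of 23 immediate-early genes, Atf3 (13.3 ± 1.81 to 37.7 ± 3.04 CPM, 1.51 ± 0.14), Dusp1 (1.15 ± 0.16) and Spry2 were higher and none lower (5 and 0 adjusted over the list alone), and 20 did not pass, with a median of 0.31 (camera adjusted p = 0.000230, and adjusted p = 0.630 with an estimated correlation). This median was 0.55 without WT replicate 1 and 0.19 without WT replicate 2, where Spry2 was not called (adjusted p = 0.105). Of 22 p53 targets, Perp (1.26 ± 0.18), Tnfrsf10b (0.77 ± 0.12, on the stretch of chromosome 14) and Pmaip1 (0.68 ± 0.16) were higher, and the list did not pass (camera adjusted p = 0.0502). Pmaip1 was not called without WT replicate 2 (adjusted p = 0.0961). Among 9 antiviral genes, Oas1a (-1.83 ± 0.31) and the RNA sensor gene Ddx58 (-0.83 ± 0.18) were lower and none higher (3 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.0479, and adjusted p = 0.630 with an estimated correlation). The antiviral call was lost without WT replicate 1 (adjusted p = 0.0884) and without KO replicate 2 (0.199, with a median of -0.23).

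Imprinted genes were among the most changed, in both directions. The maternally expressed non-coding genes of the Dlk1-Dio3 cluster on chromosome 12 fell together: Meg3 from 133 ± 11.4 to 22.3 ± 4.83 CPM (-2.57 ± 0.14, adjusted p = 0.000564), Rian from 397 ± 7.58 to 68.4 ± 18.7 CPM (-2.53 ± 0.17) and Mirg from 147 ± 11.2 to 24.9 ± 9.88 CPM (-2.54 ± 0.21). They span 109541001 to 109571726, 109603940 to 109661716 and 109729764 to 109749460. In all, 9 of 26 imprinted genes were higher and 3 lower (12 and 3 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.0479, and adjusted p = 0.802 with an estimated correlation). The list's call was lost without WT replicate 2 (adjusted p = 0.930, median 0.23), KO replicate 1 (0.404, median 0.16) or KO replicate 2 (0.156, median 0.58). Of 18 germline genes that are silenced by DNA methylation, 5 were lower and none higher (6 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.0118, and adjusted p = 0.630 with an estimated correlation). Tuba3a fell by 1.92 ± 0.26, the germ cell regulator Dazl by 1.38 ± 0.25, and the meiotic genes Majin and Sycp3 by 1.38 ± 0.28 and 0.76 ± 0.16. The germline call was lost without WT replicate 2 (adjusted p = 0.0514, median -0.0838) and without KO replicate 2 (0.172, median -0.14); without WT replicate 2 the adjusted p of Majin was 0.0658 and that of Sycp3 0.116.

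SAGA and the other general transcription complexes held 0 or 1 call each in the edgeR fit without a batch term. Among 23 SAGA subunits tested, edgeR, DESeq2 and limma voom called 0, with 3 at an unadjusted p under 0.05 in edgeR; the list's median was -0.02 (camera adjusted p = 0.817). Sf3b3 stood at 525 ± 26.3 CPM in WT and 519 ± 29.1 in KO, and the acetyltransferase gene Kat2b at 211 ± 8.23 and 159 ± 23.7 CPM (log2 fold change -0.40, adjusted p = 0.0702). For Kat2b this fold change was -0.26 without KO replicate 1. Kat2b passed the threshold without KO replicate 2 (-0.56), with no low-count filter (-0.39) and with the batch term (adjusted p = 1.09e-07), which gave 5 SAGA calls, Supt3 included. The 12 subunits of ATAC, a related acetyltransferase complex, and the 17 of TFIID and TFIIA held 0 calls in each of the same tools, with 2 and 2 at an unadjusted p under 0.05 in edgeR and 2 and 4 calls with the batch term (camera adjusted p = 0.903 for both). Of 31 Mediator subunits Med4 was higher (0.53 ± 0.09), and it lies on the stretch of chromosome 14 (camera adjusted p = 0.431).

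The mitotic list had a median of -0.17 over 20 genes and 0 single calls in edgeR, DESeq2 and limma voom, with 5 at an unadjusted p under 0.05 in edgeR and 7 calls with the batch term (camera adjusted p = 0.0479, and adjusted p = 0.757 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.167), WT replicate 2 (0.0538) or KO replicate 2 (0.244). Among 20 genes of the mitochondrial genome the median was -0.36, and the tRNA genes mt-Tw (-1.38 ± 0.25) and mt-Tt (-0.87 ± 0.19) were lower (camera adjusted p = 0.00105, and adjusted p = 0.856 with an estimated correlation; 0.117 without WT replicate 1, the library with the highest mitochondrial share). The median was -0.24 without WT replicate 1, -0.13 without KO replicate 1 and -0.63 without KO replicate 2. The remaining lists were not called by camera. Among them, the stress gene Asns (-0.57 ± 0.11) and the amino acid transporter gene Slc7a3 (-0.72 ± 0.13) were the 2 lower of 22 ATF4 targets (adjusted p = 0.223), and the chaperone gene Dnajc3, on the stretch of chromosome 14, was the 1 higher of 19 (0.63, adjusted p = 0.947). The glycolytic gene Pfkp fell from 349 ± 34.1 to 162 ± 32.6 CPM and P4ha1 rose by 0.39 among 23 genes of glycolysis and hypoxia (adjusted p = 0.740). The lysosomal regulator gene Tfeb (-0.73) and Rragd (-0.66) fell and Ctsl (0.62) rose among 21 lysosome genes (adjusted p = 0.903). Of 15 BMP targets Id1 rose by 0.91 and Smad6 fell by 0.81 (adjusted p = 0.366), and of 14 Wnt targets Lef1 fell by 0.74 ± 0.09 (adjusted p = 0.431). Without WT replicate 2 the adjusted p of Asns was 0.0892 and that of Ctsl 0.0552, and P4ha1 was not called without either WT library (highest adjusted p = 0.274). Rpl39l (0.72) was the 1 call among 76 ribosomal protein genes (adjusted p = 0.354), and Hist1h2af (-0.38) the 1 among 56 replication histone genes (0.364), lost in DESeq2 and in 3 of the 4 fits that leave out a library (highest adjusted p = 0.222). Of 328 Zfp genes 9 were higher and 2 lower, with Zfp459 at -0.99, Zfp618 at 0.88, Zfp800 at 0.77 and Zfp560 at 0.76 (adjusted p = 0.188). Calls by edgeR and DESeq2 in the lists for MYC and ribosome biogenesis, heat shock, cholesterol synthesis, DNA replication and Hox genes were 0 of 26, 15, 22, 19 and 5 tested genes, apart from 1 MYC list gene in DESeq2, with 1, 3, 5, 0 and 0 at an unadjusted p under 0.05 in edgeR and 3, 4, 6, 1 and 0 calls with the batch term (camera adjusted p = 0.947, 0.947, 0.129, 0.947 and 0.947). No clustered protocadherin gene passed the count filter. For the neural, ATAC, MYC and replication lists the median, the mean and the direction of the test did not all have the same sign.

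Called genes were unevenly spread over the genome, and the distal parts of 2 chromosomes shifted as blocks. On chromosome 14 110 of 625 tested genes were higher (Fisher's exact test, adjusted p = 4.58e-39), and on chromosome 17 77 of 762 were lower (adjusted p = 1.59e-12). A scan along each chromosome, made after these counts were seen, placed the shift on chromosome 14 between 63519651 (Mtmr9) and 122159604 (Tm9sf2), and on chromosome 17 between 71869442 (Alk) and 94877497, the end of the last gene scanned. The median log2 fold change was 0.59 over 163 genes on chromosome 14 (95% bootstrap interval 0.56 to 0.63, 93.9% of genes positive) and -0.88 over 81 genes on chromosome 17 (-0.95 to -0.82, 93.8% negative), in a scan of genes of at least 2 CPM (permutation p adjusted over 20 chromosomes = 0.00333 for each). Each KO library showed both shifts against the WT mean, 0.56 and 0.59 on chromosome 14 and -0.95 and -0.83 on chromosome 17. Between libraries of 1 genotype the scan also passed on both chromosomes, outside these intervals and at smaller shifts. They were -0.20 in WT and -0.22 in KO on chromosome 14 (permutation, adjusted p = 0.00999 and 0.00666). On chromosome 17 they were -0.17 and -0.10 (permutation, adjusted p = 0.00799 and 0.00666). This p alone therefore does not set the genotypes apart. An interval on X also met the scan's rule and is given further on. The Y-linked list fell with 4 of 6 tested genes lower (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.03e-13, and adjusted p = 0.630 with an estimated correlation). Beside Zfy1, Uty fell from 299 ± 22.6 to 86.5 ± 19.9 CPM (-1.79 ± 0.15), Ddx3y by 1.42 ± 0.13 and Eif2s3y by 0.56 ± 0.11, and without WT replicate 2 the adjusted p of Eif2s3y was 0.0779. Supt3 itself lies outside the shifted part of chromosome 17, and 175 genes within 10 Mb of it had a median of -0.05 (-0.09 to 0.01). Outside both stretches, the chromosome ends beyond them and the Y chromosome, 580 genes were higher and 604 lower of 16480.

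**Figure D4:**
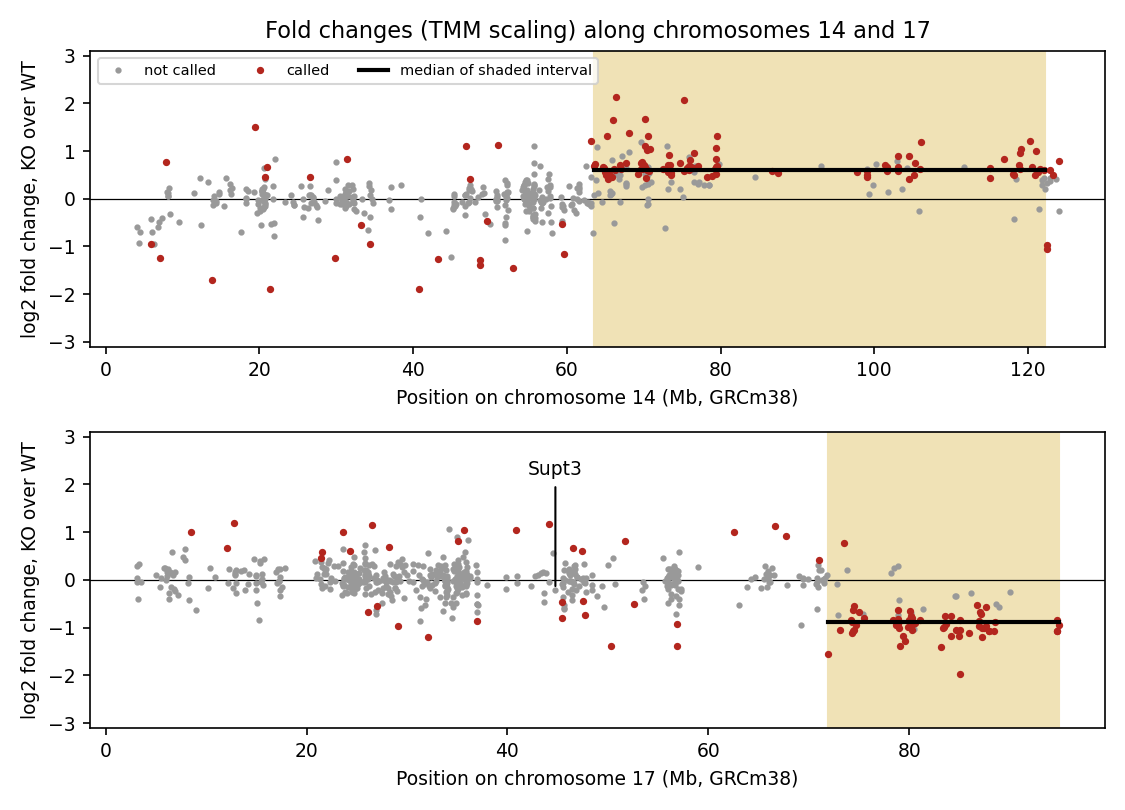
Log2 fold change of KO over WT with TMM scaling (vertical axis) against gene position in Mb (horizontal axis) on chromosomes 14 and 17 for genes of at least 2 CPM, with called genes in red and the others in grey. The shaded intervals are those found by the scan, and the thick lines mark their medians of 0.59 and -0.88.

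On the spike-in scale, which keeps any change of total output, few genes passed. Of 16789 genes, 17 differed, 1 higher and 16 lower, with 634 at an unadjusted p under 0.05. All 17 were also called with TMM scaling. Those that the naming rule gives were Zfy1 (-3.18 ± 0.70, adjusted p = 0.0154) and Catsperg1 (-2.80, adjusted p = 0.0336); the 1 higher gene, Gm21060, was chosen after its values were seen and had 0 CPM in WT and 0.70 CPM in KO. The median log2 fold change over all genes was -0.23, with 78.8% of genes negative, so that the named genes above are changes relative to that shift. Of the 80 named genes called with TMM scaling, 2 passed the test on this scale. All 80 kept their sign. This shows no agreement, because the smallest rise among them, 0.39 for P4ha1, was larger in size than the shift of -0.23. In simulated libraries with the same counts and spread this test recovered 0% of genes changed by 0.5, 1 or 2 on the log2 scale, while with TMM scaling 32.8%, 82.1% and 100% were recovered. Limma voom called 8 higher and 122 lower genes, protein-coding genes alone gave 1 and 2, and leaving out a library left 0 or 1 call. The batch term for the pairs of fewer and more counted reads, added after the data were seen, gave 816 higher and 6009 lower. With 1 residual degree of freedom and pairs taken from the same data, these 2 counts are weak evidence. The median without WT replicate 2 or KO replicate 1 turned positive (0.18 and 0.09).

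The authors' deposited table gives the same contrast with spike-in size factors. An adjusted p under 0.05 was given by the authors for 8 genes: Plagl1 was higher, and Meg3, Rian, Mirg, Zfy1, B830012L14Rik, Gm37899 and 2410152P15Rik were lower. Their shrunken log2 fold changes in the authors' deposited table included 1.62 for Plagl1, -1.92 for Meg3 and -2.07 for Zfy1. The edgeR fit on the spike-in scale called 2 of the 8, Zfy1 and 2410152P15Rik, while DESeq2 with the same factors and edgeR with TMM scaling each called all 8. Signs matched those of the edgeR spike-in fit for 99.9% of 16789 genes. This match was largely fixed in advance, because both fits use the same counts and S. pombe scaling. With the edgeR TMM fit the share was 70.1%.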

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

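The batch term and the fits without distal 14, distal 17 and Y genes were chosen after the data were seen. The other alternatives were planned. The fit with the batch term has 1 residual degree of freedom and takes its pairs from the same data, so its p-values and counts are weak evidence. No paired analysis was possible because the labels carry no replicate numbers; the batch term sets WT replicate 1 with KO replicate 1 and WT replicate 2 with KO replicate 2 by counted reads, a hint from the data (correlation of deviations 0.27). For the TMM counts (680 higher, 675 lower), DESeq2, limma voom, the 1 CPM filter, protein-coding genes, 3 other scalings and the fit without distal 14, distal 17 and Y stayed within 1.5 times, and 1082 of the 1355 genes were shared with DESeq2 and 1320 with limma voom. With no low-count filter the counts were 1260 and 1200, with a fold change of at least 2 they were 208 and 310 by construction, and with the batch term 2214 and 2093. Leaving out a library gave 379 to 1481 higher and 439 to 1342 lower genes. For the spike-in counts (1 higher, 16 lower), limma voom gave 8 and 122, no filter 0 and 29 (1060 at an unadjusted p under 0.05), the 1 CPM filter 0 and 8 (512 unadjusted), protein-coding genes 1 and 2, and the batch term 816 and 6009. Leaving out a library gave 0 higher and 0 to 1 lower genes in edgeR (208 to 704 unadjusted). The other spike-in factors gave the main counts. The cause of these changes was not tested. The log2 ratio of mouse to S. pombe counts ranged from -0.66 to 0.19, and the spike-in median from -0.66 to 0.18, when a library was left out, and other scalings and gene sets moved neither by over 0.02. Supt3 kept its negative sign throughout; it passed the threshold with the batch term (-0.22) and without KO replicate 2 (range over left-out libraries -0.31 to -0.13). Camera called 14 lists, 0 with an estimated correlation (lowest adjusted p = 0.630), 0 with fry (lowest adjusted p = 0.157), 13 with fry in either direction, 11 to 16 with a library left out and 12 without distal 14, distal 17 and Y genes. Called members of lists numbered 111 with TMM and 1 with spike-in scaling, and 340 with TMM scaling and the batch term. Of the authors' 8 genes, edgeR on the spike-in scale called 2, and DESeq2 on that scale, edgeR with TMM and DESeq2 with mouse factors each called 8. Of 80 named genes called, 65 were called in all 4 fits that left out a library. Uncalled genes that turned sign were Sf3b3 (-0.0755 to 0.0378, with 0.0358 without WT replicate 2), mt-Cytb (-0.31 to 0.0284) and mt-Nd1 (-0.39 to 0.0797). Depth limits what can be said of genes under 2 CPM; 3159 of them outside the shifted stretches had a median of -0.14, and the cause was not tested.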

Other observations

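The chromosome scan, the S. pombe gene test and the 8 tests of explanations in this part were chosen after the results were seen, as were the genes named; the edgeR fit and the mouse to S. pombe ratio were set before. The fall of Meg3, Rian and Mirg extended to other genes of the cluster. Gm34081 (-3.12 ± 0.41), Mir434 (-3.42 ± 0.49) and B830012L14Rik (-2.51 ± 0.23) on chromosome 12 were lower in both KO libraries, with edgeR adjusted p of 0.00365, 0.00513 and 0.00109. Dlk1, the protein-coding gene at one end of the cluster, stood at 0.90 ± 0.39 CPM in WT and 0.83 ± 0.02 in KO, and Dio3 at the other end at 1.61 ± 0.42 and 0.44 ± 0.09. Of the imprinted genes outside this cluster, H19 (1.64), Peg10 (1.13), Airn (1.20) and Grb10 (0.66) rose. On the Y chromosome, Usp9y had a log2 fold change of 0.61 ± 0.25 (edgeR adjusted p = 0.187), opposite in sign to its neighbours Uty and Ddx3y. On the X chromosome the scan placed 26 genes from Usp26 to Fmr1nb at a median of -0.28, with -0.39 in KO replicate 1 and -0.13 in KO replicate 2. Among 5662 S. pombe genes, which should not differ by genotype, edgeR called 2 and 6.08% had an unadjusted p under 0.05.

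The first pattern is the shift of distal chromosomes 14 and 17. Gene length and GC content do not account for it, since medians corrected for both were 0.58 (0.54 to 0.62) and -0.89 (-0.96 to -0.82). A loss of 1 of 2 copies of distal 17 in every KO cell predicts -1 and stays open: the median of -0.88 over all 81 genes (-0.95 to -0.82) lies above it, but the 27 genes with the highest expression had -0.99 (-1.05 to -0.93), against -0.83 and -0.73 for the 27 of middle and the 27 of lowest expression. An extra copy of distal 14 is a candidate explanation: 163 expressed genes had a median of 0.59 (0.56 to 0.63) where 3 copies against 2 predict 0.58, but 28 genes under 2 CPM had a median of 0.15 (0.02 to 0.28) against -0.14 for such genes elsewhere. Both tests of copies were reworded after their values were seen: as first worded they counted against an extra copy of 14 and against a loss on 17. The extra copy of 14 is left open because genes of low expression exclude nothing. The loss on 17 is left open because the interval of its 27 most expressed genes holds -1. That of the 27 genes of middle expression (-0.89 to -0.68) does not hold it.

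The second pattern is the fall of the Meg3, Rian and Mirg RNAs. A loss of copies reaching beyond the cluster is argued against by 84 genes within 5 Mb on either side, whose median was -0.0346 (-0.11 to 0.02). A switch of the cluster to paternal-type expression, which could raise Dlk1 and Dio3, cannot be told apart from other losses of these RNAs. Dio3 was called lower (-1.81, edgeR adjusted p = 0.0375), opposite to such a rise, and Dlk1 was not called (-0.06). Both genes lie under 2 CPM, so their values do not decide the question. An effect of Supt3 loss on the cluster stays open as untested.

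The third pattern is the lower mouse to S. pombe ratio in KO. Variation between libraries in the spike-in or in recovered RNA may account for it, because libraries of the same genotype differed by at least 0.79 on the log2 scale against -0.24 between genotypes. A lower output per KO cell cannot be told apart from it: the highest KO library lay 0.58 above the lowest WT library, with 2 libraries per genotype.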
